A study of Mus musculus with 2 samples.

How the data were processed

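The facial prominence was dissected from B6NCrl mouse embryos at embryonic day 15.5, and the authors immunoprecipitated chromatin with an antibody to H3K27ac and deposited 4 peak lists on build mm10. Per the file headers, peaks were called for each replicate with its own control and for the reads of both replicates together. The fold enrichment of a peak was deposited by the authors as a ratio over the control. The significance of a peak was deposited by the authors as −log10 p and −log10 q. The lowest −log10 p in the lists was 2.02, so the lists were filtered on that value and not on −log10 q, and weak peaks were part of every list. The aligner, the peak caller, their versions and their parameters were not given in the sources used here. The rule that made the replicated list from the pooled list and the replicates was not stated either, and 9906 of its 59787 peaks did not overlap a peak of each replicate by 50% of either peak. A list of called peaks holds no signal between peaks, so a region without a peak was not known to be without the mark. Library depth changes how many weak peaks are called and was not in the files.

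Peaks on chrM and on unplaced scaffolds were left out, which kept 105701, 103255, 137184 and 59787 peaks of replicate 1, replicate 2, the pooled list and the replicated list. Protein-coding genes and transcript starts were taken from GENCODE M21, and sequence from the matching mouse genome. A gene was called marked when a replicated peak lay within 1 kb of any of its transcript starts. A peak was called distal when it lay over 2.5 kb from every annotated start, and it was assigned to the nearest protein-coding TSS within 100 kb. The gene lists held 350 symbols, of which 349 were found in the annotation and Ahsp was not. The 21 lists, the comparisons, the tests, the rule for named genes and most of the other settings given below were fixed before the data were examined.

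The rule named, in each list, the 3 marked members with the highest mean promoter enrichment and the alphabetically first 2 members without a peak of either replicate there. It also named the 10 genes with the most distal peaks, the genes nearest to the 10 highest domains, and the 5 genes each with the highest promoter enrichment and the widest promoter peak. Enrichment of a gene is the highest fold enrichment within 1 kb of a TSS in each replicate's own list, given as mean ± SD of the replicates. The share of marked genes in a list was compared with 10000 random lists of genes from the same deciles of promoter GC content. Distal peaks were compared as the mean of log2 of the number plus 1 against 10000 random lists from the same deciles of territory length. Both tests were two-sided with Benjamini-Hochberg adjustment over the 21 lists and a threshold of 0.05. The change between replicates was given as a percentile of random lists matched on mean enrichment, for lists with at least 5 genes in both replicates, because 2 libraries of a single group allow no test of a condition. Motifs were exact consensus matches in 500 bp around peak summits, set against windows matched on GC content in 2% bins and lying outside all pooled peaks. Distal peaks within 12.5 kb were joined into domains and ranked by the sum of width times fold enrichment.

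Other settings tried were overlaps of 50%, only peaks with −log10 q of 5 or more, equal numbers of top peaks, either replicate alone, all pooled peaks, TSS windows of 500 bp and 2.5 kb, distances of 50 kb and 250 kb, random lists without matching, the most 5-prime start only, 200 bp motif windows and joining within 5 kb. Added after the data were examined were the replicated peaks that met a rule of 50% overlap with both replicates, promoter marking without shared peaks, ranks in place of ratios between replicates, and motif windows with few repeats. The comparison of each motif with permuted forms of its consensus was also added then. The list comparisons were tested on simulated data with 200 lists of 20 genes each, at a single size of effect and without adjustment over lists. For promoter marking 2% of unchanged lists and 90% of raised lists were called, and 50% of unchanged lists were called without GC matching. For distal peaks the percentages were 4.5% and 68.5%, and 70.5% of unchanged lists without matching on territory length. For the difference between replicates they were 2% and 99%. Simulated genes were independent and effects only raised values, so lowered lists and clustered genes were not tested. Lists were drawn from genes of high GC content or long territory, so the calls without matching were built in. Matching between replicates used random groups and was not tested. Of planted exact copies of 3 consensuses 100% were found, which was certain in advance and tested only the search. The matched windows and the permuted forms were not simulated. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, samtools 1.23.1, pysam 0.24.0 and bedtools 2.31.1.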

Results

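The series measured acetylation of lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, in the embryonic facial prominence of mice of strain B6NCrl at embryonic day 15.5. Tissue from healthy embryos of both sexes was pooled into 2 biological replicates, 1 of 78 embryos and 1 of 62 embryos. The series held 1 group and no other condition, stage or tissue. The comparisons were therefore between the replicates, between promoters and distal regions, and between lists of genes within the tissue. The deposited files held 105721 peaks for replicate 1, 103265 for replicate 2, 137199 for the pooled reads and 59796 for the authors' replicated list, all on mouse build mm10. Sequencing depth was unknown, because the files hold no counts. The fold enrichment and p of each peak were the authors' own values. They were used to describe and rank peaks within a list, and values of fold enrichment from different lists are set side by side below as descriptions only.

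The strongest marks recurred in both pools of facial tissue, and weak marks often did not. Of the peaks of replicate 1, 58.8% (95% interval 58.5 to 59.1) overlapped a peak of replicate 2, and of the peaks of replicate 2, 59.9% (59.6 to 60.2) overlapped a peak of replicate 1. The intervals treated peaks as independent and did not measure variation between pools. Random placement gave 3.53% and 3.59%. In the quintile of peaks with the highest fold enrichment the shared percentages were 98.0% and 98.5%, and in the lowest quintile they were 35.7% and 34.3%. Peaks within 1 kb of the transcription start site (TSS) of a protein-coding gene were shared at 82.7% and 82.9%, and distal peaks at 52.2% and 53.1%. Over overlapping peaks the fold enrichment of the replicates had a Spearman rho of 0.607 and a Pearson r of 0.757 on the log2 scale. When an overlap had to cover at least 50% of both peaks, the shared percentages fell to 34.2% and 35.0%.

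The replicated list held the strong part of the pooled list. It contained 43.6% of the pooled peaks, from 4.02% in the weakest quintile by fold enrichment through 28.6% in the middle quintile to 99.8% in the strongest. The median width was 655 bp in the replicated list and 327 bp in the pooled list. The median fold enrichment was 3.88 in the replicated list and 2.83 in the pooled list.

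Promoters carried wider and stronger marks than distal regions in both pools. Promoter-proximal peaks had a median fold enrichment of 4.93 ± 0.141 and distal peaks, over 2.5 kb from every annotated TSS, 3.28 ± 0.109 (mean ± SD of the replicates, n = 2). The ratio was 1.50 ± 0.00688, and the median widths were 501 ± 1.41 bp and 260 ± 4.24 bp (n = 2). Of the replicated peaks, 15462 (25.9%) lay within 1 kb of a protein-coding TSS, in windows that make up 2.37% of the genome, and 35439 (59.3%) were distal. Introns of protein-coding genes held 51.8% of the distal replicated peaks against 34.1% of random positions, and the space between genes held 38.7% against 57.6%. With all pooled peaks the proximal share was 15.5%.

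Of 21853 protein-coding genes, 11969 (54.8%) had a replicated peak within 1 kb of a TSS and are called marked below. The highest promoter enrichments were those of the transcription factor genes Sp3 (46.9 ± 1.34), Zfp143 (45.4 ± 0.466) and Klf7 (42.8 ± 6.12), of Hmgb2 (44.0 ± 1.41), which encodes a chromatin protein, and of the histone gene Hist4h4 (43.9 ± 2.26, n = 2 for each). The widest replicated peak over a TSS covered 21049 bp at Col1a1, the gene of a type I collagen chain and the main matrix protein of bone, with its TSS at chr11:94936224. Peaks of 16063 bp at Tbx2, 14370 bp at Tnrc18, 14068 bp at Trio and 12249 bp at Kdm6b came next.

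Genes of the cranial mesenchyme and of the fibroblast matrix were marked at nearly every promoter. Of 24 cranial mesenchyme regulators, 23 were marked (95.8%), where GC-matched random lists averaged 67.8%. Alx4 (21.1 ± 4.61, TSS at chr2:93642384), Prrx1 (19.5 ± 4.04, chr1:163313710) and Twist1 (13.8 ± 0.883, chr12:33957671), which encode transcription factors needed for the skull and face, had the highest enrichments (n = 2), and Barx1 had no peak in either replicate. All 18 fibroblast matrix genes were marked against 49.2% of random genes, led by the growth factor receptor gene Pdgfra (21.2 ± 1.09) and the collagen genes Col5a1 (19.8 ± 1.46) and Col3a1 (16.5 ± 1.23, n = 2). The peak counted for Fbn1 in this list also reached the TSS of Gm9913. All 20 housekeeping genes were marked against 65.8%, with Ywhaz (37.6 ± 0.183), Actb (35.2 ± 0.860) and Tuba1b (28.2 ± 1.99) highest (n = 2).

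Each list was compared with 10000 random gene lists of the same size and promoter GC content in a two-sided permutation test, for which the smallest possible p was 0.0002, and p was adjusted over the 21 lists. The adjusted p from this permutation test was 0.00168 for cranial mesenchyme regulators, 0.00105 for fibroblast matrix and 0.0021 for housekeeping genes. These 3 lists were marked more often than random genes, and 6 lists were marked less often.

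Hox genes, which pattern the trunk and hindbrain, and genes of heart, liver, neurons, forebrain and germ cells made up those 6 lists. Of 39 Hox genes 2 were marked (5.13%) against 70.9% of random genes, of 15 cardiac genes 2 against 71.9%, and of 17 liver genes 1 against 47.2% (permutation adjusted p = 0.00105 for each). The Hox genes lie in clusters A to D, and random lists were drawn as single genes, so the Hox p treats neighbours as independent. Of 18 neuron genes 5 were marked against 64.0%, of 12 forebrain genes 3 against 68.0%, and of 13 germ cell genes 2 against 56.6% (permutation adjusted p = 0.0078, 0.00787 and 0.00793). Bcl11b (19.3 ± 4.24), Otx1 (8.44 ± 0.376) and Emx2 (7.83 ± 0.790) were the marked forebrain genes, and Irx4 (3.93 ± 0.258) and Myh7 (3.68 ± 1.64) the marked cardiac genes (n = 2). Alb and Afp, the genes of albumin and alpha-fetoprotein, had no peak at their promoters, and neither did Gata4, Mybpc3, Emx1, Eomes, Dcx, Elavl3, Acrv1 or Ddx4. Among neuron genes Tubb3 (4.10 ± 1.01), Gap43 (4.05 ± 0.425) and Elavl4 (3.44 ± 0.0422) were highest (n = 2). The single marked liver gene, Apoh (6.42 ± 1.17, n = 2), shared its peak with Prkca. In the own peaks of replicates 1 and 2, 4 and 5 cardiac genes and 1 and 3 liver genes had a promoter peak. Both lists were still called lower with either replicate left out. Of the marked germ cell genes, Dazl had 5.40 ± 0.138 (n = 2), and Tnp2, with a peak in replicate 2 alone (3.21), shared the replicated peak with Socs1. Without GC matching the permutation adjusted p was 0.113 for forebrain and 0.0645 for neuron genes, and without peaks that reach the TSS of another gene it was 0.106 for each, so those calls ended.

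**Figure D1:**
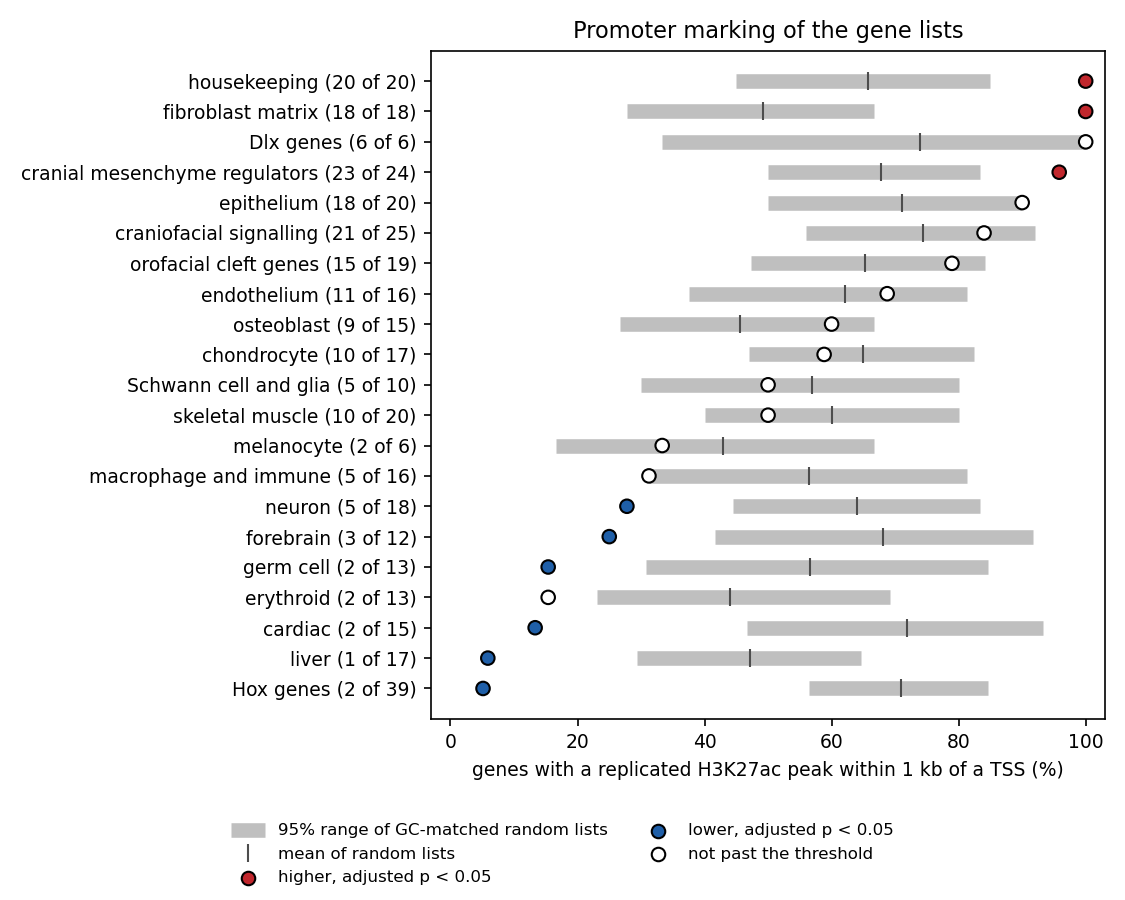
Share of each gene list with a replicated H3K27ac peak within 1 kb of a TSS (horizontal axis, percent of genes) for the 21 lists (vertical axis). Points show the observed share and bars the 95% range of 10000 GC-matched random lists.

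The other 12 lists did not differ from GC-matched random genes after correction. All 6 Dlx genes, which pattern the jaws, were marked (permutation adjusted p = 0.46), with Dlx5 at 8.56 ± 0.545, Dlx1 at 6.11 ± 2.31 and Dlx2 at 4.71 ± 1.19 (n = 2). Of 25 craniofacial signalling genes 21 were marked, led by Axin2 (33.0 ± 0.450), Jag1 (23.6 ± 1.78) and Wnt5a (23.3 ± 0.166), while Shh and Fgf8 had no promoter peak (n = 2; permutation adjusted p = 0.501, but 0.0163 without matching and 0.0336 without shared peaks, where the list was called higher). Of 19 orofacial cleft genes 15 were marked, led by Tgfb3 (21.8 ± 0.475), Nectin1 (17.1 ± 0.204) and Fgfr1 (17.0 ± 2.48, n = 2), while Crispld2 and Foxe1 were not (permutation adjusted p = 0.405). Of 15 osteoblast genes 9 were marked, with Col1a1 (17.5 ± 4.97), Sparc (15.9 ± 2.47) and Col1a2 (14.4 ± 1.84) highest and the mineralization genes Bglap and Mepe without a peak (n = 2; permutation adjusted p = 0.451). Of 17 chondrocyte genes 10 were marked, among them Sox9 (13.2 ± 0.844), the master regulator of cartilage, Sox6 (6.85 ± 1.26) and Col11a1 (5.77 ± 0.978, n = 2), but not Col10a1 or Comp (permutation adjusted p = 0.845).

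Epithelial genes were marked at 18 of 20 promoters, among them the splicing regulators Esrp1 (9.45 ± 0.706) and Esrp2 (7.91 ± 0.557) and the transcription factor Grhl2 (8.79 ± 1.80, n = 2; permutation adjusted p = 0.106). This list was called higher under other settings, with a permutation adjusted p of 0.0042 without replicate 1, 0.0332 without replicate 2, 0.0042 for pooled peaks, 0.0302 within 2.5 kb, 0.0063 without matching and 0.007 without shared peaks. Of 20 skeletal muscle genes 10 were marked, with Pax7 at 5.39 ± 1.47, Tnnt1 at 4.32 ± 0.0368 and Tnni1 at 3.98 ± 0.308 (n = 2), and Actc1 and Myf6 were not (permutation adjusted p = 0.545). The highest replicated peak of Tnni1 (chr1:135798964 to 135799347) also lay away from its most 5-prime start (chr1:135783065). Replicate 1 alone had 16 of these muscle genes marked and replicate 2 alone 9, and with all pooled peaks 90% were marked, above random lists (permutation adjusted p = 0.0357). Of 16 endothelial genes 11 were marked, with Eng at 8.20 ± 0.660, Fli1 at 7.36 ± 0.526 and Erg at 5.60 ± 0.393, and Tie1 was not (n = 2; permutation adjusted p = 0.845, but 0.0357 and called higher with all pooled peaks). Of 13 erythroid genes 2 were marked, Klf1 (8.08 ± 1.22) and Ank1 (4.70 ± 0.0794), while Alas2 and Epor were not (n = 2; permutation adjusted p = 0.0571). The highest peak of Ank1 (chr8:23137864 to 23140264) lay at another annotated start, far from its most 5-prime start (chr8:22974844). The erythroid list was called lower within 500 bp (permutation adjusted p = 0.0107), within 2.5 kb (0.042), without replicate 1 (0.0357) and without matching (0.0205). Of 16 macrophage and immune genes 5 were marked, including Aif1 (5.10 ± 0.0956), Cd68 (4.03 ± 0.232) and Laptm5 (3.21 ± 0.586), while the complement genes C1qa and C1qb were not (n = 2; permutation adjusted p = 0.104). That list was called lower within 500 bp (permutation adjusted p = 0.00924), with −log10 q of 5 or more (0.003) and with the rule of 50% overlap (0.0122). Of 10 Schwann cell and glia genes 5 were marked, with Erbb3 at 12.0 ± 3.95, Mpz at 11.8 ± 0.384 and Egr2 at 5.90 ± 1.55 (n = 2), and Cdh19 and Fabp7 were not (permutation adjusted p = 0.906). Of 6 melanocyte genes 2 were marked, Pmel (18.7 ± 7.29) and Mitf (3.08 ± 0.366), and Tyr and Mlana were not (n = 2; permutation adjusted p = 0.937). The peak of Mpz also reached the TSS of Sdhc, and that of Pmel the TSS of Cdk2.

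Hox clusters A, B and C held few called peaks and cluster D held several. The replicates had 1 and 0 peaks in cluster A, 0 and 0 in B, 0 and 2 in C, and 4 and 5 in D. No gene was marked among 11 of cluster A, 10 of cluster B and 9 of cluster C, and 2 of 9 genes were marked in cluster D, Hoxd8 (3.68 ± 0.261, TSS at chr2:74704615) and Hoxd3 (3.49 ± 1.22, chr2:74711927, n = 2). Replicate 2 alone had a peak of 2.38 near Hoxc13. In the 200 kb around cluster A (chr6:52108235 to 52308234) replicate 1 had 1 peak, with a fold enrichment of 2.30, and replicate 2 had 0. In 200 kb around Alx4 the replicates had 52 and 59 peaks and the replicated list 29.

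**Figure D2:**
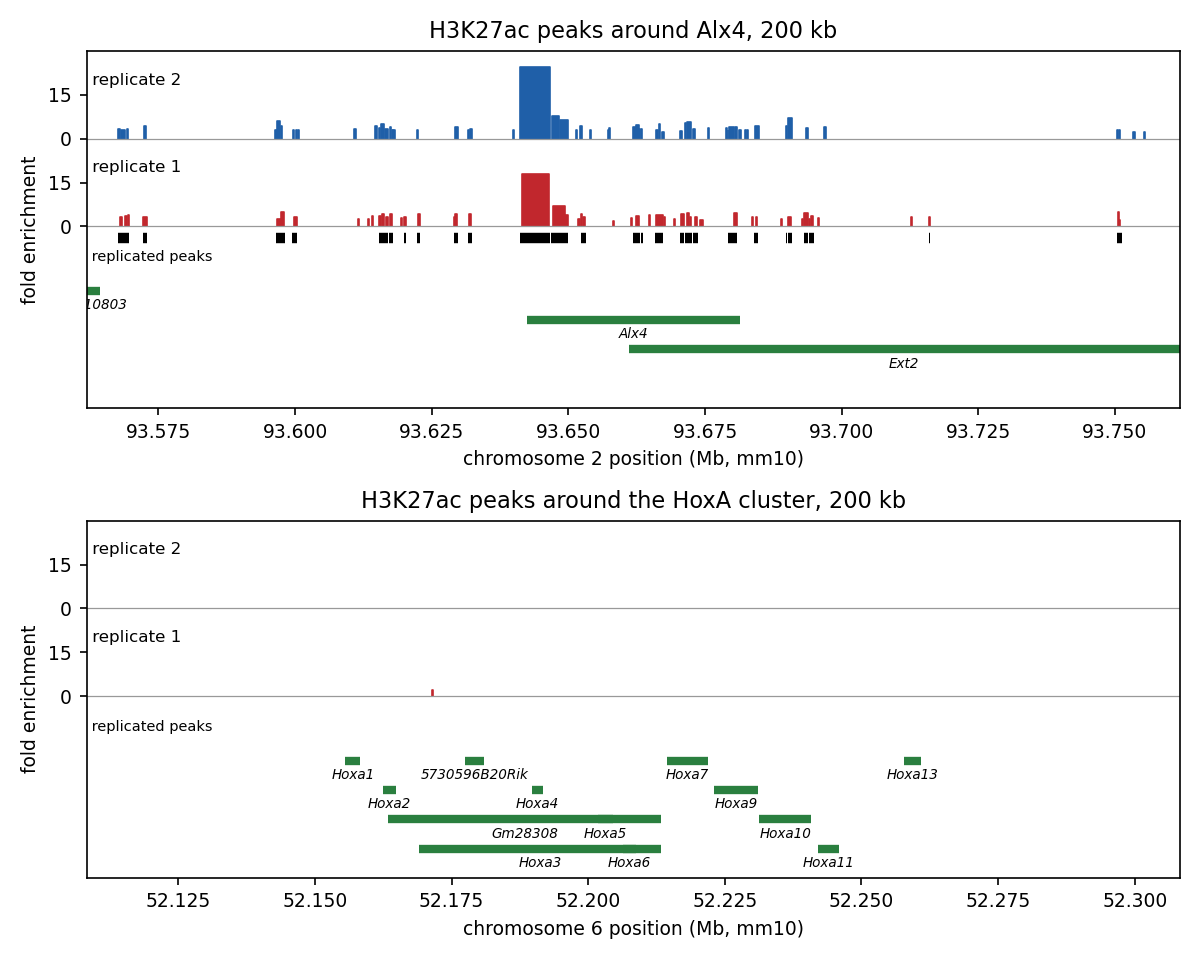
H3K27ac peaks in 200 kb of build mm10 around Alx4 and around the HoxA cluster. The horizontal axis is genomic position and the vertical axis fold enrichment, coloured bars are peaks of each replicate, black bars replicated peaks and green bars genes.

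Distal marks gathered around the same mesenchymal and matrix genes and around epithelial, signalling and cleft genes. The geometric mean over a list of the number of distal peaks plus 1 was 2.86 times that of random lists matched on territory length for fibroblast matrix (139 peaks in total, 30 at Col5a1) and 2.80 times for cranial mesenchyme regulators (162 peaks, 17 at Twist1 and 15 at Alx4). It was 2.64 times for epithelium (107 peaks, 12 at Grhl2), 2.49 times for craniofacial signalling (209 peaks, 15 at Axin2) and 2.13 times for orofacial cleft genes (105 peaks, 15 at Nectin1). Each of these 5 lists had a permutation adjusted p of 0.00084. Osteoblast genes (1.75 times, 60 peaks), endothelial genes (1.71 times, 61 peaks, 20 at Erg) and housekeeping genes (1.44 times, 30 peaks) followed, with permutation adjusted p of 0.027, 0.0352 and 0.0252. The tests were two-sided against 10000 random lists, adjusted over the 21 lists. Random genes were not matched on promoter marking, so an excess shared by marked genes in general was not separated. With only peaks of −log10 q of 5 or more the permutation adjusted p was 0.0672 for osteoblast and 0.106 for endothelium, and with peaks within 250 kb it was 0.0567 for endothelium. Without replicate 2 the permutation adjusted p was 0.0635 for housekeeping genes, and without matching it was 0.325. Peak totals were larger in the own lists of replicates 1 and 2, at 306 and 309 for cranial mesenchyme regulators and 260 and 233 for fibroblast matrix. They were 183 and 176 for epithelium, 377 and 358 for craniofacial signalling and 188 and 198 for orofacial cleft genes.

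**Figure D3:**
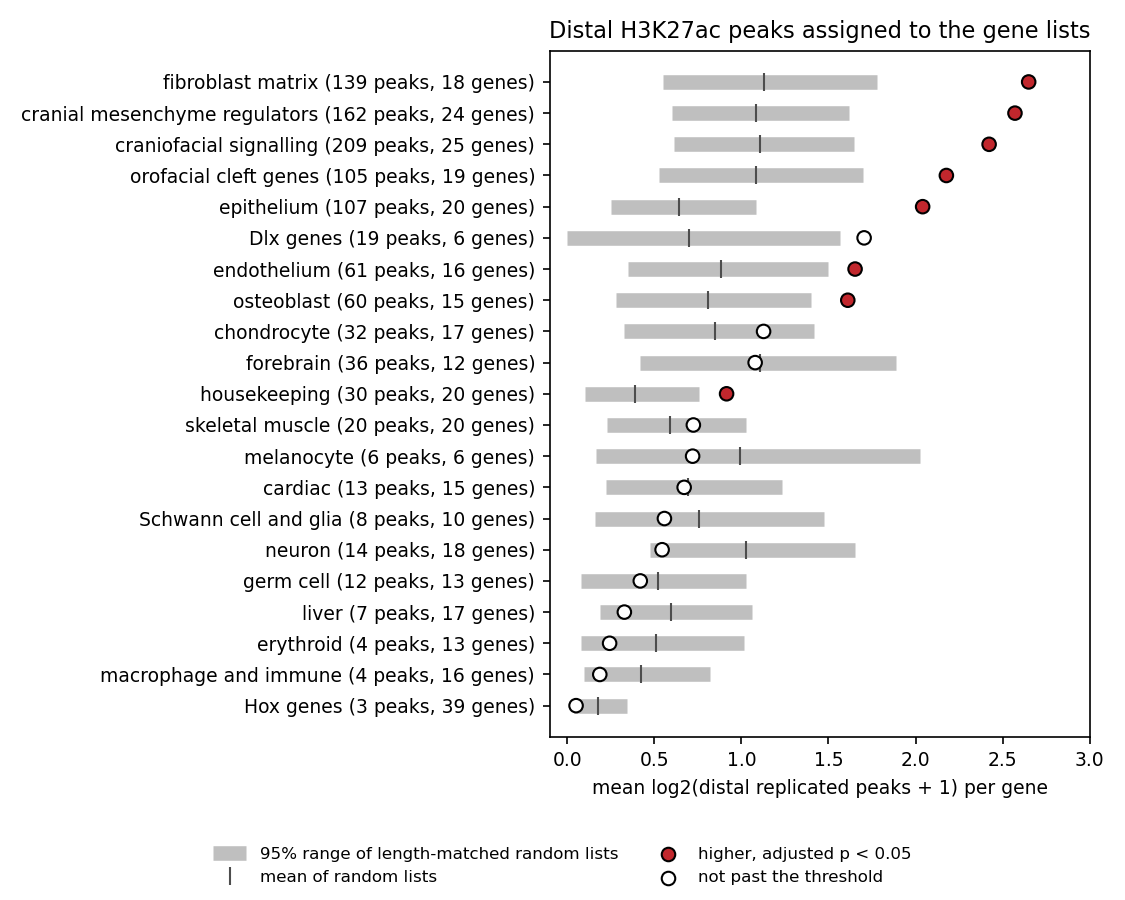
Mean of log2 of the number of distal replicated H3K27ac peaks plus 1 per gene (horizontal axis) for the 21 lists (vertical axis). Points show the list and bars the 95% range of 10000 random lists matched on territory length.

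The other 13 lists did not differ from random genes in distal peaks after correction. Dlx genes had 19 peaks (ratio 2.01, permutation adjusted p = 0.063), 9 of them at Dlx2, and were called higher without replicate 1 (0.0264), without replicate 2 (0.0462) and with pooled peaks (0.0308). Chondrocyte genes had 32 peaks (1.21, permutation adjusted p = 0.456), skeletal muscle genes 20 (1.10, 0.676) and forebrain genes 36 (0.980, 0.985), 21 of them at Bcl11b. Ratios under 1 were seen for Hox (0.917, permutation adjusted p = 0.214), neuron (0.715, 0.193), erythroid (0.832, 0.413), liver (0.832, 0.402), macrophage and immune (0.850, 0.402), melanocyte (0.828, 0.749), Schwann cell and glia (0.872, 0.749), germ cell (0.931, 0.786) and cardiac genes (0.986, 0.985).

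The single genes with the most distal replicated peaks were Tcf4 (56), Gse1 (54), Sh3pxd2a (50), Boc (48), Tgfbr3 (48), Arid5b (45), 2010111I01Rik (44), Nfib (44), Rbfox2 (43) and Frmd4a (41). Boc encodes a co-receptor of hedgehog signalling, Tgfbr3 a co-receptor of transforming growth factor beta, and Nfib a nuclear factor I protein. Their own promoters were enriched 35.0 ± 3.19 (Nfib), 25.9 ± 0.976 (Boc) and 17.7 ± 1.88 (Tgfbr3, n = 2).

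Among genes with a promoter peak in both pools, the lists shifted by small amounts between the pools. After removal of the median log2 ratio of replicate 2 to replicate 1, which was 0.06, the median shift was 0.26 for chondrocyte genes and −0.30 for Dlx genes. Shifts of other lists were 0.14 for orofacial cleft genes, −0.14 for fibroblast matrix, −0.19 for osteoblast, −0.12 for skeletal muscle, 0.07 for cranial mesenchyme regulators, −0.08 for craniofacial signalling, 0.02 for epithelium, −0.03 for endothelium, 0.08 for neuron and 0.06 for housekeeping genes. No list of the 12 with at least 5 genes in both replicates lay outside the central 95% of 10000 random lists matched on mean enrichment. The closest were chondrocyte genes at percentile 96.2 and Dlx genes at percentile 5.52. Within 2.5 kb of a TSS, Schwann cell and glia genes reached percentile 99.1 with a shift of 0.48, and without matching chondrocyte genes passed the upper bound of the range.

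Sites of MEF2 and NFI factors had the highest ratios in the distal marked regions of the face among motifs with more than a few sites. The MEF2 consensus occurred in 1.24% of 35430 distal replicated peaks and 0.559% of GC-matched windows, a ratio of 2.21 (1.97 ± 0.0815 in the replicates' own peaks, n = 2). The NFI consensus occurred in 2.23% and 1.13%, a ratio of 1.98 (1.82 ± 0.110, n = 2). The E-box CAGCTG, a site of basic helix-loop-helix factors, occurred in 32.8% of peaks, a ratio of 1.31 (1.27 ± 0.0211, n = 2). These 3 motifs had higher ratios than every permuted form of their own consensus, a criterion added after the data were examined, and the margin for CAGCTG was 1.31 against 1.30. Each motif had 20 permuted forms (13 for TAATTA) and no correction over motifs was made, so some could pass by chance. All 3 read the same on both strands, as do several that did not pass, and permuted forms need not. AP-1 (1.32), AP-2 (1.31), CTCF (1.29), FOX (1.22), the homeodomain site TAATTA (1.17 ± 0.00824 in the replicates, n = 2), RUNX (1.16), ETS (1.12), SOX (1.10), the E-box CATCTG (1.07) and TEAD (1.03) did not pass it. ETS, found in 64 peaks and 57 windows, was higher in the replicates' own peaks (1.76 ± 0.0297, n = 2) and did not pass in either. GATA (0.860), NFY (0.679) and the shuffled control (0.827) were less frequent in peaks than in windows. NFI and CAGCTG each lost the call without replicate 2 and in the 200 bp around the summit, NFI also with −log10 q of 5 or more and CAGCTG also without replicate 1. MEF2 kept it in all of these. AP-2 passed it in the 200 bp windows (1.41 against 1.32), and TEAD (1.06 against 1.02) and FOX (1.25 against 1.23) in windows with few repeats. In the 200 bp windows CTCF fell to 0.712 and TEAD to 0.942, and without replicate 2 TEAD was 0.997. In the main analysis HNF1 (ratio 3.00, from 3 peaks and 1 window) was left out of the plot and of this order.

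**Figure D4:**
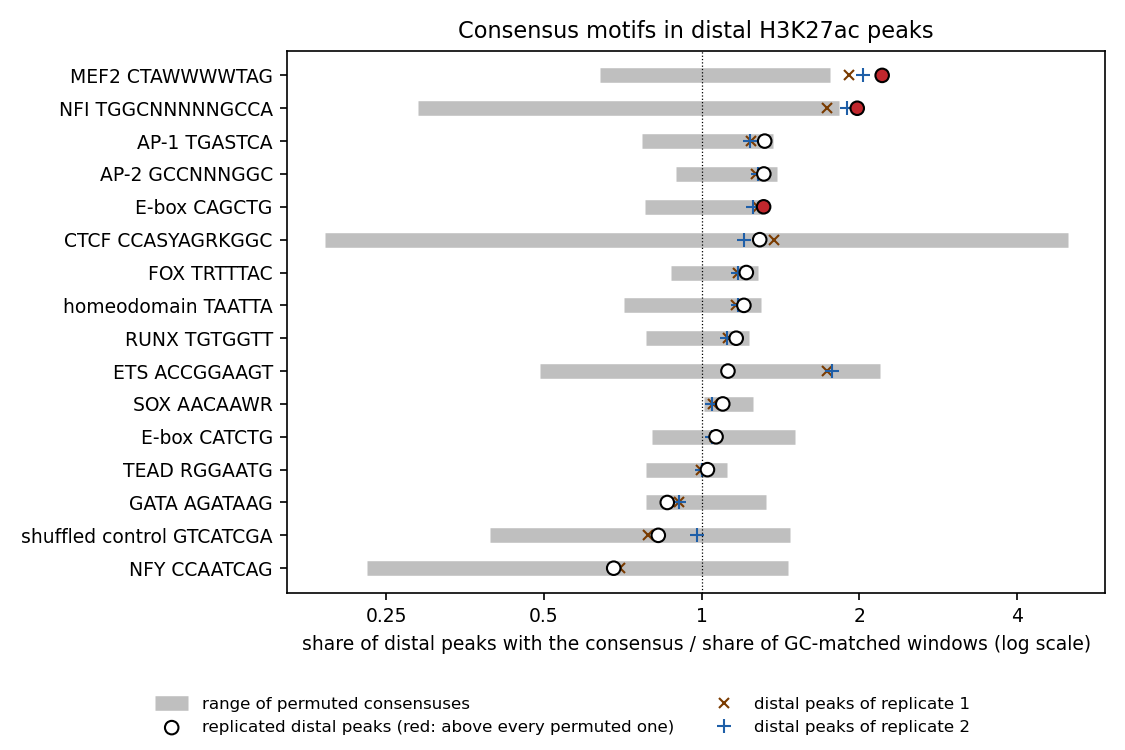
Ratio of the share of distal H3K27ac peaks with a consensus to the share of GC-matched windows (horizontal axis) for each motif (vertical axis). Points show the replicated list and each replicate, and bars the range of the permuted consensuses.

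The domains of distal marks with the highest scores included ones at the retinoid receptor gene Rxra and at Ski, a regulator of transforming growth factor beta signalling. Distal peaks joined with their neighbours formed 15458 domains, of which 8063 held 1 peak and 1542 held 5 or more, and the scores of the replicates had a Spearman rho of 0.827. The highest domain covered 96.3 kb (chr1:86419972 to 86516317, 26 peaks) and overlapped Tex44 and Nmur1. Tex44 itself was not marked, and the nearest marked promoter was that of Ptma (29.6 ± 0.119, n = 2), 10409 bp away. The next were a 142 kb domain that overlapped Dnm3 (37 peaks, chr1:162072079 to 162213989), a 132 kb domain beside Zfp36l1 (29 peaks), and 144 kb and 105 kb domains at Nxn (46 peaks) and at Ski (30 peaks). Domains near Lrrc74a (16 peaks), at Rxra (30 peaks), near Npvf (49 peaks), at Ncor2 (24 peaks) and near Irf2bp2 (17 peaks) completed the first 10. The domain assigned to Npvf began 260500 bp from that gene and the nearest marked promoter was Nfe2l3, 347521 bp away. With peaks joined within 5 kb, the genes nearest to the 20 highest domains included 6 of the 19 found here.

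The X chromosome carried fewer marks than the autosomes. It held 4.61 replicated peaks per Mb against 24.0, and 334 of 948 X genes (35.2%) were marked against 56.1% of autosomal genes, a ratio of 0.628. The ratio was 0.635 in replicate 1 and 0.633 in replicate 2. The median promoter enrichment of marked X genes was 6.04 and 6.43 in the replicates, against 8.01 and 8.34 on autosomes. Among named X genes, the erythroid gene Alas2 and the neuron gene Dcx had no promoter peak, and the housekeeping gene Pgk1 (10.9 ± 2.04, n = 2), chosen after its values were seen, was marked.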

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

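All values in this part were looked at without a planned test. The mitochondrial chromosome, which has no histones, held 13 peaks in replicate 1, 1 in replicate 2, 3 in the replicated list and 5 in the pooled list, and none of them was used. The highest fold enrichment among them was 2.03 in replicate 1, 1.33 in replicate 2 and 1.42 in the other lists.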

How the results depend on the processing

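The added settings, and the motif criterion, were chosen after the results were seen. Counts were called the same within 1.5 times of their main value, and other values within a spread, mostly that between the replicates. List and motif tests were the same when their call was kept. Of 82 comparisons of the main values with other settings, 55 were the same and 27 moved. Of 849 for distal peaks of lists and named genes, 570 were the same and 270 moved. Of 390 for promoter enrichment of named genes, 387 were the same. The cause was not tested where values moved, unless a setting moved them by construction. The mean shared percentage of the replicates was 59.3 in the main analysis, 52.6 and 34.6 with overlaps of 50% of either or both peaks, and 73.9 with −log10 q of 5 or more. The rho was 0.607, and 0.772 and 0.727 under the last pair of settings. Pooled peaks in the replicated list were 43.6%, and 93.8% with −log10 q of 5 or more. The proximal share was 25.9%, 24.0% within 500 bp, 30.3% within 2.5 kb, 31.2% with −log10 q of 5 or more, 15.5% for pooled peaks, 21.5% with the most 5-prime start and 19.8% to 20.3% with a replicate left out. The proximal to distal ratio was 1.50 and 1.60 with −log10 q of 5 or more. Lists marked more often numbered 3, and 4 within 2.5 kb and with either replicate left out, 6 for pooled peaks, 5 without matching and 5 without shared peaks, with epithelium added in each. Lists marked less often numbered 6, and ranged from 4 without shared peaks to 8 within 500 bp, where erythroid and macrophage and immune genes were added. Lists with fewer distal peaks numbered 0, and 1 without matching. Lists outside the range between replicates numbered 0, and 1 each without matching and within 2.5 kb. Motifs above every permuted form numbered 3, 5 with few repeats, and 2 each with −log10 q of 5 or more and in 200 bp windows. Without replicate 2 they numbered 1, and without replicate 1 they numbered 3, including HNF1 from 4 peaks and 1 window. Top domains shared numbered 19, 6 within 5 kb and 11 to 15 with a replicate left out. The X ratio was 0.628, 0.651 for pooled peaks and 0.633 to 0.635 with a replicate left out. Skeletal muscle promoter marking was 50% in the main analysis, not different from random lists, and 90% for all pooled peaks, called above them. Depth was not given, so its effect on weak peaks and on promoters without a peak could not be measured. No paired analysis was possible because the series held 1 group.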

Other observations

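The tests of gene families and of non-coding genes, and the test of promoter GC content on the X chromosome, were chosen after the data were seen, as were the counts of weak promoters and of further peaks of the same gene, and muscle was singled out of the 21 lists after its counts were seen. Genes were grouped by the letters of their symbol before the first digit or hyphen, which gave 141 families of at least 15 genes, and a first grouping that also dropped a last letter had given 183. In a two-sided permutation test against GC-matched genes, 40 families were marked more often and 31 less often after adjustment over the 141 families (38 and 39 of 183 with the first grouping). The smallest possible p was 0.001 with 2000 random lists, which gave an adjusted p of 0.0041. Family members that lie side by side were treated as independent genes, so p can be too small for clustered families. Genes of mitochondrial ribosomal proteins were marked at 48 of 49 (Mrpl) and 27 of 29 (Mrps) promoters. Genes of cytosolic ribosomal proteins were marked at 41 of 44 (Rps) and 46 of 54 (Rpl), histone genes (Hist) at 58 of 67, and lysine demethylase genes (Kdm), with a median enrichment of 17.0, at 17 of 18. Zinc finger genes (Zfp) were marked at 307 of 394. GC-matched random lists averaged 53.1% for Zfp, and between 54.2% (Hist) and 65.8% (Kdm) for the other families named so far. Olfactory receptor genes (Olfr) were marked at 1 of 1134 promoters, vomeronasal receptor genes (Vmn) at 1 of 331, keratin-associated genes (Krtap) at 1 of 57 and keratin genes (Krt) at 7 of 53. GC-matched lists averaged only 8.84% for Olfr and less than that for Vmn. These receptor families were therefore below a share that was already far under the 54.8% of all genes. For Krtap and Krt the matched averages were 32.7% and 56.2%. Rhox genes, with 0 of 34, and Serpina genes, with 0 of 24, had no replicated peak at a promoter, against matched averages of 50.3% and 50.8%. Wnt genes were marked at 9 of 19, against 76.8% (permutation adjusted p = 0.0323).

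Away from protein-coding starts, 752 of 5356 lincRNA genes (14.0%), 300 of 1788 antisense genes (16.8%) and 162 of 1846 microRNA genes (8.78%) had a replicated peak within 1 kb. Malat1 (33.0 ± 6.66) and Neat1 (25.4 ± 0.0403), the genes of abundant nuclear RNAs, and Mirlet7i (30.9 ± 0.125) were strongly marked (n = 2). Dnm3os, the transcript that carries Mir199a-2, had 24.2 ± 0.818, and Mir199b had 23.9 ± 0.990 (n = 2). The Dnm3os start lay at chr1:162219868, 75712 bp from the nearest protein-coding start and beside the domain of 142 kb in Dnm3.

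More skeletal muscle promoters had a called peak in replicate 1 (16 of 20) than in replicate 2 (9), at percentile 99.8 of lists matched on pooled promoter enrichment, but the difference did not pass correction (permutation p = 0.0064 two-sided, adjusted p = 0.134 over the 21 lists). A general excess of weak peaks in replicate 1 is unlikely to be the cause, because 12431 genes were marked in replicate 1 and 12439 in replicate 2, and 623 and 602 in the lowest decile of pooled enrichment. For 20 genes of the same pooled enrichment those counts give a mean difference of 0.110, against the 7 observed. The range of 2 standard errors of that mean (−0.246 to 0.466) does not measure the spread of single lists, which the percentile above does. A larger share of muscle in the first pool might have raised distal peaks too, but these numbered 33 and 42, at percentile 7.78, which meets a bound of 50 set before but lies inside the central 95%, and that bound was judged too loose after the value was seen. That explanation stays open, and so does chance, since muscle was the most extreme of the 21 lists.

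Some promoters of genes listed for other tissues or cell types carried peaks, and a peak that reaches a neighbouring gene could be the reason. The 9 lists examined were erythroid, macrophage and immune, neuron, Schwann cell and glia, melanocyte, forebrain, cardiac, liver and germ cell. For 23 of their 27 marked members, such as Bcl11b, Erbb3 and Klf1, the highest peak reached no other protein-coding start within 1 kb. A peak that reaches such a start is unlikely to be the cause for these. Starts farther away, non-coding starts and enhancers of a neighbour were not examined. The other 4 members (14.8%) were fewer than the mean of 21.5% for GC-matched marked genes, inside the 95% range of 7.41% to 37.0%. For these 4, Mpz, Pmel, Apoh and Tnp2, 0 had a further peak of their own, so a neighbour could explain them and cannot be told apart from a mark of their own. A small share of cells of these types in the tissue was not tested and stays open, as do other sources of the peaks.

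The X chromosome had fewer marked genes than GC content gives. Of its genes 35.2% were marked, against 45.2% (95% range 42.6 to 47.7) of GC-matched lists (permutation p = 0.002 two-sided, 1000 lists), so promoter GC content is unlikely to be the whole cause. Without families that have 4 or more members on a chromosome, 46.4% of 582 X genes were marked against 54.5% (50.9 to 58.1) of matched lists. Of the autosomal genes kept, 66.4% were marked. A gap remained, so clustered gene families are unlikely to be the whole cause, and whether they explain a part was not settled. Families were taken from the first 4 letters of the symbol, which need not group related genes. A lower yield of reads from the single X of male cells might add to the gap. Fold enrichment, a ratio over the control, was also lower at marked X genes (6.04 and 6.43 against 8.01 and 8.34). How the control entered that ratio was not given, so these values do not decide whether a lower yield took part. Other causes were not examined. With both sexes in each pool, the parts of the X in male and in female cells remained untested.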
